A study of Dictyostelium discoideum with 40 samples.

How the data were processed

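Gene expression of the social amoeba Dictyostelium discoideum was measured on 2-colour Agilent oligonucleotide arrays. Per the labels' protocols, amoebae of strain NC105.1 carrying red fluorescent protein (NC105.1-RFP) were grown on Klebsiella bacteria, mixed in equal amounts with unlabelled amoebae, spread on 2 agar plates as biological replicates, and left to develop for 4, 8, 12, 16 or 20 h. The fluorescent cells were then recovered by cell sorting after mechanical disaggregation, and total RNA of the NC105.1-RFP cells was amplified, labelled and hybridised against 1 common reference pooled from several times of development of NC105.1-RFP. The partner was unlabelled NC105.1 in the control, called the self mix here, and the strain NC28.1 in the chimera. Each of the 20 plates was hybridised on 2 arrays, once with the sample in Cy5 and once in Cy3, which gave 40 arrays. Groups, times, replicate numbers and dyes were taken from the labels. The labels call the plates biological replicates but speak of amoebae mixed and then spread on both plates, so p-values measured the spread between plates, and not that between separately grown and mixed cultures.

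The deposited array files held, per the file headers, the output of Agilent Feature Extraction. The median pixel intensity of each spot and of its local background was used in both channels, and had not been normalised per the file headers. The processed intensity of each channel had, per the file headers, been background-subtracted, detrended and dye-normalised by that software, and the deposited log10 ratio of red over green, made from the processed signals per the file headers, was not used. The deposited series table held log2 ratios. Set against the processed signals of the same arrays, they were log2 of sample over reference, not centred, with column medians from -0.116 to 0.232 and a correlation of 0.999996 or more on every array. limma was named in the submitters' processing notes without a version, and its settings are not given in the sources used here.

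The plan written before the data were examined called for mean spot signals, while the files held median signals, which were used. Background was corrected by the normexp method with an offset of 50, with parameters fitted on all spots, and each array was normalised by loess with control spots and spots marked as outliers at weight 0. These spots were then left out, with at most 207 outliers on any array, and no spot was saturated. Ratios were turned to log2 of sample over reference by the dyes in the labels, and the 2 arrays of a plate were averaged. The lowest correlation between 2 arrays of one orientation was -0.30 with the sample in Cy5 and -0.33 with the sample in Cy3. The direction was kept because the labels state the dyes and early and late plates can oppose each other against a pooled reference. Each array had 43803 non-control spots for 32199 probes, of which 11361 were spotted more than once and averaged. A probe was kept where the sample channel was well above background on both arrays of at least 2 plates, which left 28583 probes and 10037 of 10858 genes, and 10022 genes had values on all 20 plates and were tested. A gene's value was the mean over its kept probes. Of 9564 genes with 2 or more kept probes, 7 had probes that moved in opposite directions by over 1 log2 unit each between 4 and 20 h. Gene identifiers came from the array files. Names were added from a table of assembly dicty_2.7 of strain AX4, which held 10766 of the identifiers and lacked 92, and 3198 of the tested genes had a symbol beyond the identifier. The array files name no genome build, so no coordinates are printed, and probe sequences designed on one strain can bind another strain less well.

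Differences were tested with limma 3.58.1 in R 4.3.3, with files read by the package data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9 in Python 3.11.15, on the 20 plates, with 1 mean per mix and time and 10 residual degrees of freedom shared by all 10 groups. All p-values of single genes are two-sided limma values, adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The comparisons were chimera minus self averaged over the 5 times and at each time, the mix by time interaction (an F test), and 20 h minus 4 h in self mixes. For a gene whose probes were not well above background on any array of one group, the fold was given as a lower bound. It set the mean of the brighter group against a floor, after Aquantile scaling of the channels. The floor was, per array, the higher of the dimmest signal well above background and the gene's own signal. Where the brighter group was itself not above background on some arrays, the bound is approximate. Of 22 gene lists fixed with the plan, 19 had at least 5 measured members and were tested with camera (preset correlation of 0.01, and an estimated correlation) and fry, adjusted over the 19 lists. The lists were aggregation and cAMP signalling, tgr allorecognition family, prespore and spore, prestalk and stalk, lysosomal and bacteria-digesting enzymes, cytosolic and mitochondrial ribosomal proteins, DNA replication and cell cycle, histones, proteasome, heat-shock proteins and chaperonin, antioxidant enzymes, polyketide synthases, actin cytoskeleton, ABC transporters, autophagy, respiratory chain and ATP synthase, counting factor and cheater genes, and calcium-binding cbp proteins. The hssA and sigN small-protein families and the discoidins had 1 measured member each and retrotransposons 0, so these were not tested. The means of lists and of the first principal component were also tested by exact two-sided permutation of the mix labels within times, with 7776 splits. On simulated data with 200 of 10022 genes changed, the averaged comparison called 70.1% of genes changed by 0.5 log2, 94.0% of those changed by 1 and 100% of those changed by 2. The comparison at 4 h called 10.4%, 61.2% and 90.9%. Unchanged genes were called in 12 and 5 cases. The simulated noise was independent between genes, with 1 spread per gene for all groups and no deviant plate or distorted array. These shares can therefore be too high for the real data.

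Genes named in the text followed a rule fixed with the plan. Among genes with a symbol it took, for the averaged comparison, the largest differences among called genes with the same sign at 4 or more times, or the 10 of smallest p if fewer than 10 passed, which was the case. For each time it took up to 3 called genes in each direction, for the interaction up to 4, for 20 h minus 4 h the 8 largest rises and 8 largest falls, for each list up to 4 called members of the averaged comparison, and always 14 markers of stage and cell type, of which carA, staB and dscA were not measured here. Not every gene the rule took is described. Genes without a symbol, list members given as examples and genes named beyond this were chosen after their values were seen.

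On 6 of the 40 arrays the background model was distorted. Its fitted background SD was 354 to 1930 on those arrays, against at most 104 and a median of 2.80 on the others, and log ratios were compressed, with an SD across probes as low as 0.408. These were the Cy5 arrays of self 4 h replicate 1, self 8 h replicate 1 and chimera 16 h replicate 2, and the Cy3 arrays of self 8 h replicate 2, chimera 12 h replicate 2 and self 16 h replicate 1. The planned setting was kept as the main one. After the counts of changed genes had been seen, the model was refitted. Its parameters were then estimated without spots whose local background was over 2 times the array's median, at most 141 spots in a channel. Refitted values are given beside the planned ones for most results between mixes, and for only some of 20 h minus 4 h. Alternatives in the plan were the processed signals, median centring in place of loess, Aquantile scaling, no filter and a stricter filter on dim probes, the brightest probe per gene, the deposited series table, all 40 arrays with the plate as a random block, the replicate number and the slide as blocks, each dye orientation alone, a trended and robust variance, fits of 2 groups alone, and leaving out each plate in turn.

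Signal quality was read from the scanner's flags. Between 69.9% and 88.5% of probes were well above background in the sample channel of an array, and the median spot signal was 100.0 to 739.5 in green and 209 to 2079 in red. Precision is limited by the number of arrays. The 2 dye orientations of a plate correlated across genes with r from 0.563 to 0.973, with a median of 0.945, and with 0.922 or more after the refit. No pair of plates held identical values. The file headers gave 6 slide numbers, and the arrays fell into 10 combinations of slide number and scan day, each with 4 arrays of which 2 were chimeras and 2 self mixes. No such combination held both mixes of 1 time, so within-slide values of a single time could not be had, and the scan day coincided with the dye orientation.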

Results

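The data were 40 two-colour arrays of NC105.1-RFP cells sorted out of mixes with their own parent strain (self mix) or with the other wild strain NC28.1 (chimera). RNA was taken at 4, 8, 12, 16 and 20 h of development, the interval in which starving amoebae aggregate, form a slug and build a fruiting body of stalk and spores. There were 10 groups of 2 plates, and each plate value was the mean of 2 dye-swapped arrays. Values are log2 ratios of the sample over a common reference of the same strain. The series was designed to ask how a strain's gene expression differs when it develops with a non-self partner in place of its own kind. Replicate plates correlated across genes with r from 0.696 in chimeras at 16 h and 0.841 in chimeras at 20 h to 0.969 in self mixes at 20 h.

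Development of the sorted strain among its own kind was compared first, since it gives the scale of change and checks the time labels. Between 4 and 20 h, stalk and spore genes rose by up to over 100-fold while genes of the translation machinery fell. The extracellular matrix genes of the stalk lineage ecmD and ecmA had log2 differences of 7.30 ± 0.51 (SE) and 6.89 ± 0.69, which are 158-fold and 119-fold. The cellulose synthase gene dcsA rose by 6.27 ± 0.64 and sigK by 6.01 ± 0.63. Rises of 6.28 to 6.70 were also found for hssB, 7E and st15. The gene cmr was not well above background on any of the 4 arrays at 4 h and was at least 34.6-fold higher at 20 h. Among the largest falls were cytosolic ribosomal protein genes, led by rpl12 at -5.23 ± 0.44 and rps12 at -5.22 ± 0.42, followed by rpl26, rps16, rpl24 and rpl21 down to -4.83. The largest fall among genes with a symbol was that of cad3, which is named for a calcium-dependent cell adhesion protein, at -5.66 ± 0.61. All 15 genes named here had an adjusted p of 0.000617 or less (n = 2 plates per time), and none lost its call in any alternative that was run. Over all genes, 5964 of 10022 genes (59.5%) were called, 3081 higher and 2883 lower at 20 h. With the refitted model 6391 were called, 3307 higher and 3084 lower. The rises named here were then larger, with ecmD at 7.93 and ecmA at 7.26, or 244-fold and 153-fold. The falls moved little, with rpl12 at -5.20 and cad3 at -5.64. Of the plates at 4 h, self replicate 1 held an array of distorted background.

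**Figure D1:**
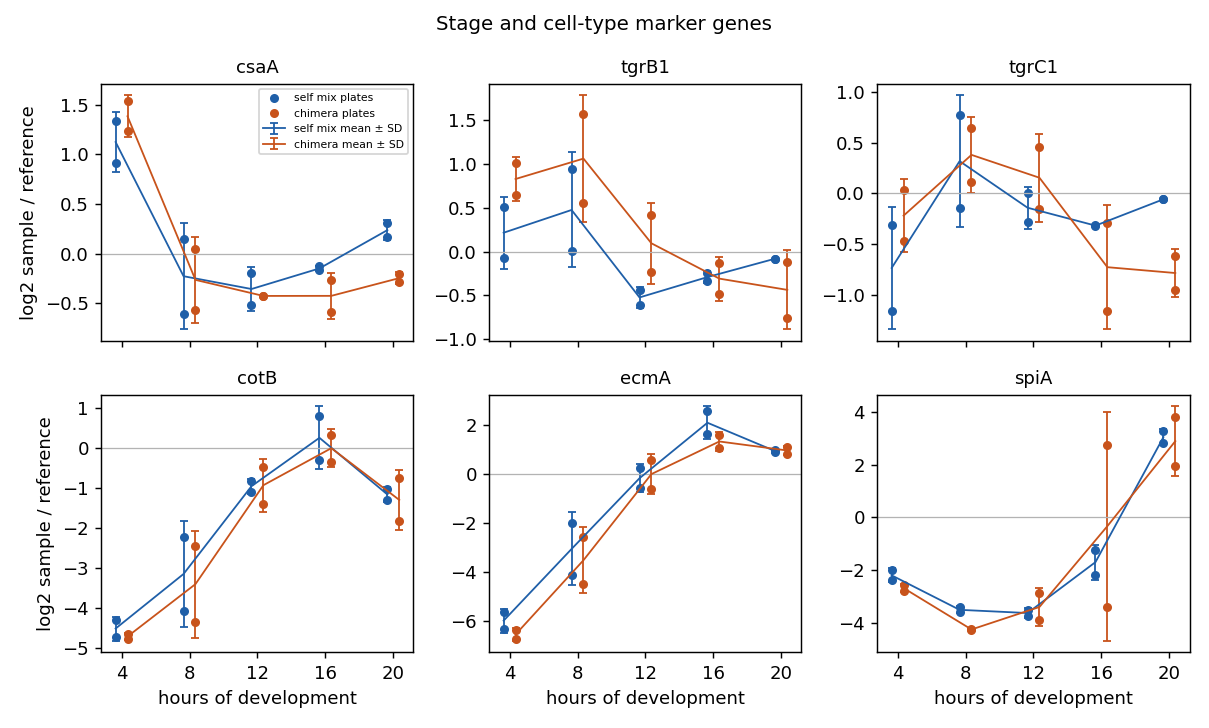
Log2 ratio of sample over reference (vertical axes) against hours of development (horizontal axes) for csaA, tgrB1, tgrC1, cotB, ecmA and spiA. Points are plates, lines join the means of 2 plates of the self mix (blue) and the chimera (orange), and bars are 1 SD. ecmA rose from -5.98 in self mixes at 4 h to 2.07 at 16 h, and the 2 chimera plates at 16 h had spiA at -3.39 and 2.74.

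Prespore and spore genes rose together in this comparison, with 13 of 14 members higher and the trehalose synthase gene tpsA at 0.20. The spore coat genes cotA, cotB and cotC had differences of 2.82 ± 0.54, 3.34 ± 0.67 and 5.15 ± 1.00, the prespore gene pspA had 3.47 ± 0.69 and the late spore gene spiA 5.23 ± 1.31. Of the 13 prestalk and stalk genes 11 rose, among them ecmB by 5.51 ± 0.71, and mybE and dmtA did not pass. Of these genes, cotB rose earlier than the late gene spiA. In self mixes cotB was at -4.50 ± 0.30 (SD, n = 2) at 4 h, -0.96 ± 0.19 at 12 h and 0.25 ± 0.78 at 16 h, while spiA stayed at or below -1.69 ± 0.66 until 16 h and reached 3.04 ± 0.31 at 20 h. The aggregation adhesion gene csaA was at 1.12 ± 0.30 at 4 h and 0.24 ± 0.10 at 20 h, a fall by 0.89 on the log2 scale (adjusted p = 0.00955). The adenylyl cyclase gene acaA (0.27 ± 0.21, SE) and the allorecognition genes tgrB1 (-0.30 ± 0.38) and tgrC1 (0.68 ± 0.38) did not pass between 4 and 20 h. Of the 25 measured members of the tgr family, these 2 recognition genes included, 15 rose, with tgrM1 at 4.11 and tgrR2 at 3.55, and none fell. Counts adjusted over the list alone were the same, 13, 11 and 15.

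The cytosolic ribosomal proteins fell in 71 of 71 cases, with a median of -4.15, the proteasome subunits in 38 of 38 with a median of -2.63, and the respiratory chain and ATP synthase subunits in 22 of 22 with a median of -1.52. Among the last 2 groups psmA5 was at -3.88 and atp5e at -3.49. Of 11 mitochondrial ribosomal proteins 8 fell, as mrpl22 did by 1.48 on the log2 scale, and mrpl34 rose by 0.50. The ABC transporters went the other way, with 25 of 53 higher, led by abcG18 at 5.63, and 7 lower, of which abcG22 at -1.59 was the lowest. For these 5 lists the counts adjusted over the list alone were 71, 38, 22, 9 and 32. camera compares a list with the other genes, while fry asks whether the genes of a list move, on balance, one way, without a comparison to other genes. With camera, 8 lists differed, namely prespore, prestalk, tgr, cytosolic and mitochondrial ribosomal, proteasome, respiratory chain and ABC transporters, with adjusted p from 4.2e-28 to 0.0116. With an estimated correlation none of the 8 held (adjusted p = 0.266 for each). This test passed 0 lists in every comparison run, even the ribosomal list here with all 71 genes called. A list that fails it is therefore not shown to be unchanged.

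Of the other lists, all but the histones held members that rose and members that fell. The lysosomal and bacteria-digesting enzymes had 9 of 15 lower, such as the lysozyme alyL at -3.64 and nagB at -3.03, and 4 higher, such as nagC at 1.86 and ctsB at 1.63. The actin cytoskeleton had 25 of 59 lower, such as abpA at -3.66, and 13 higher, such as the formin gene forJ at 3.35. The heat-shock proteins and chaperonin had 9 of 21 lower, 6 of them chaperonin subunits such as cct8 at -2.04, and 2 higher, hspB and hspC at 1.14 and 1.34. Antioxidant enzymes had 5 of 12 lower, with sodB at -4.21, and 3 higher, with sodD at 5.95, trxD at 4.33 and catB at 3.97, so that the median was -0.42 and the mean 0.02. Polyketide synthases had 8 of 17 higher, with pks25 at 4.75 and pks5 at 4.55, and 2 lower, of which stlA was at -1.76. Calcium-binding cbp proteins had 7 of 11 lower, led by cbpP at -2.68, and cbpH higher at 1.90. Counting factor and cheater genes had 3 of 6 lower, smlA at -3.89, ctnA at -3.37 and ctnC at -2.47, and 2 higher, fbxA at 1.86 and cf60 at 0.97. Aggregation genes had 5 of 18 lower, among them cadA at -3.92 and pdiA at -3.36, and 4 higher, among them gtaC at 1.23. Histones had 4 of 11 lower, led by H2Bv1 at -2.79, and 0 higher. Autophagy genes had 3 of 10 higher, led by atg9 at 1.20, and 2 lower, and DNA replication genes had 2 of 28 higher, mcm3 and rfc1, and 2 lower, pcna and cycA. None of these 11 lists passed with camera, and fry found 16 of the 19 lists to move one way on balance, all but the aggregation, DNA replication and histone lists. Adjusted over the list alone, the counts were 13, 38, 11, 8, 10, 8, 5, 9, 4, 5 and 1 in the order given.

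The chimeras were compared with self mixes in how far development had gone. Between 4 and 20 h 6466 genes changed in them, of which 5124 changed in the same direction in self mixes and 12 in the opposite one, and the log2 differences of the mixes correlated across genes with r of 0.947, where genes are not independent replicates. On the first principal component, which held 61.3% of the variance of the 20 plates, self mixes moved from -73.0 at 4 h to 77.0 at 20 h and chimeras from -84.1 to 71.3. The chimera minus self differences went both ways, at -11.1, -9.87, 11.2, 17.9 and -5.68 from 4 to 20 h. Their mean was 0.50 (exact permutation within times, two-sided p = 0.941). With the refitted background model they were 0.82, -2.52, 13.0, 17.2 and -6.28, so the gaps at 4 and 8 h shrank. The mean was then 4.45 (p = 0.518 in the same permutation). The 2 chimera plates were 30.6 apart at 16 h and 39.3 at 20 h, farther than the 2 self plates at 23.0 and 5.77. With the refitted model the 16 h plates scored 38.7 and 83.4 in chimeras and 40.2 and 47.6 in self mixes. At 16 h the chimera plate called replicate 2 was ahead, with spiA at 2.74 against -3.39 and ecmB at 3.83 against 0.80. With the refitted model its score of 83.4 lay among those of the 20 h plates. At 20 h the chimera plate called replicate 1 was behind, with a refitted score of 51.8 against 90.4 in replicate 2. Self mixes at 20 h scored 73.8 and 80.9, so 51.8 lay nearer to the other 16 h plates. The chimera means at 16 and 20 h thus each hold 1 plate that scored near the other time. The reason was not tested, and the labels were kept. Averaged over the times, none of the markers differed between mixes. The log2 differences of cotA, cotB, cotC and pspA were -0.20 ± 0.24 (SE), -0.16 ± 0.30, -0.19 ± 0.45 and -0.20 ± 0.31, those of ecmA, ecmB and spiA were -0.32 ± 0.31, -0.04 ± 0.32 and 0.04 ± 0.59, and those of csaA, acaA, tgrB1 and tgrC1 were -0.12 ± 0.11, 0.01 ± 0.09, 0.29 ± 0.17 and -0.05 ± 0.17, with adjusted p from 0.641 to 0.992.

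**Figure D2:**
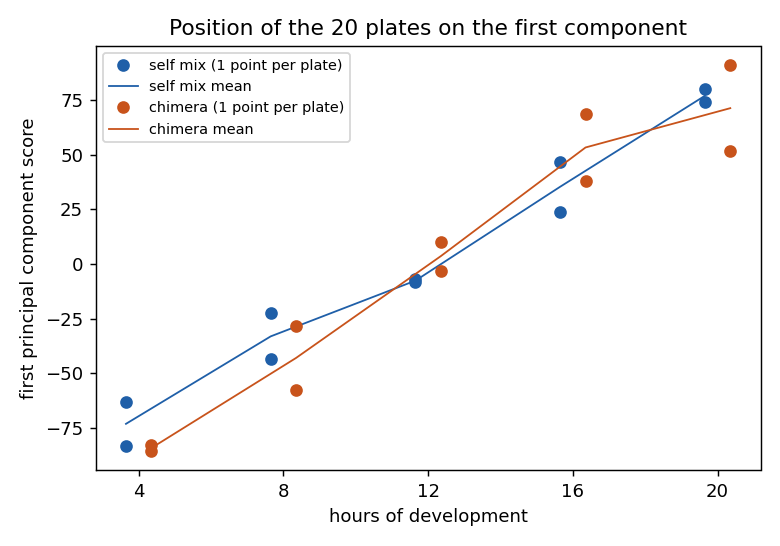
First principal component score (vertical axis, no unit) against hours of development (horizontal axis) for 10 self mix plates (blue) and 10 chimera plates (orange), with lines through the group means. With the planned values shown, self mixes went from -73.0 to 77.0 and chimeras from -84.1 to 71.3, and the 2 chimera plates were 39.3 apart at 20 h.

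Averaged over the 5 times, chimeras and self mixes differed in 11 of 10022 genes, 9 higher and 2 lower in chimeras. A pair of differences stood far above the others. The genes known by the identifiers DDB_G0288419 and DDB_G0288417, which follow each other on chromosome 5 in the table of strain AX4, had log2 differences of 4.27 ± 0.35 (SE, adjusted p = 0.000209) and 4.19 ± 0.42 (adjusted p = 0.00107). DDB_G0288419 was not well above background on any of 20 self arrays and was so on 18 of 20 chimera arrays, at least 13.1-fold higher. In chimeras it was above background on 2 of 4 arrays at 4 h and on 4 of 4 at each time from 8 to 20 h, with log2 ratios between 4.59 ± 1.53 (SD, n = 2) and 5.86 ± 1.13 at those times. DDB_G0288417 was already at 3.74 ± 2.21 at 4 h and was highest at 8 h, at 5.19 ± 0.08, with self mixes between 0.08 and 0.26, and 2 of its 3 probes were well above background on 5 of 20 self arrays. DDB_G0283429 was higher in chimeras by 2.18 ± 0.33 (SE, adjusted p = 0.0255), and fell from 4.25 ± 0.40 (SD) at 8 h to 0.66 ± 0.19 at 20 h. DDB_G0278667, not well above background on any self array and at least 3.17-fold higher in chimeras, just missed the threshold at 2.15 ± 0.37 (SE, adjusted p = 0.0504). All 4 were higher in chimeras at 5 of 5 times. By the scanner's flags, 5 probes of 4 genes were well above background on at least 18 of 20 chimera arrays and on no self array, and 0 probes showed the reverse. With a looser limit set after the values were seen, at least 15 of 20 chimera arrays and at most 1 self array, there were 11 probes of 6 genes, and again 0 the other way. On the probes of these 6 genes the reference channel was itself above background on 0 to 7 of 40 arrays, or 19 for 1 probe, so their ratios are set against a reference near background. At DDB_G0281695 the difference was 0.84 ± 0.12 (adjusted p = 0.0255), at least 1.49-fold, and at DDB_G0288951 it was 0.74 ± 0.12 (adjusted p = 0.0321).

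**Figure D3:**
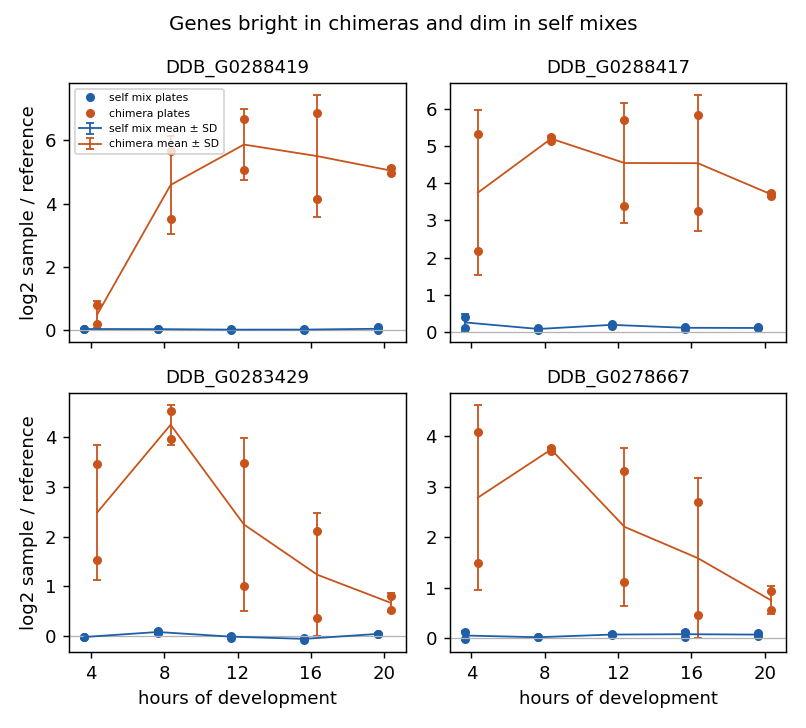
Log2 ratio of sample over reference (vertical axes) against hours of development (horizontal axes) for DDB_G0288419, DDB_G0288417, DDB_G0283429 and DDB_G0278667. Points are plates, lines join the means of 2 plates and bars are 1 SD. Means of self mixes (blue) lay between -0.07 and 0.26, and those of chimeras (orange) reached 5.86, 5.19, 4.25 and 3.73.

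Among genes with a symbol, metap1 (DDB_G0279433), which encodes a methionine aminopeptidase, was lower in chimeras by an averaged -0.38 ± 0.06 (SE, adjusted p = 0.0255), with the same sign at 5 of 5 times. The polyketide synthase gene pks13 (DDB_G0272981) was higher by 0.37 ± 0.05 (adjusted p = 0.0255). Only at 4 h were its probes above background in either mix, and the difference had the same sign at 3 of 5 times. The averaged value therefore rests on 4 h and gives no lower bound of a fold. The other 8 symbols of smallest p did not pass, with adjusted p from 0.0675 to 0.155. They were tssc1 at -0.30, the GATA factor gene gtaO at 0.42, the cysteine proteinase gene cprE at -0.41, polA at -0.42, ciao1 of cytosolic iron-sulphur assembly at -0.23, dtfA at -0.28, the aldo-keto reductase gene alrA at -0.53 and adprt1A, of the poly(ADP-ribose) polymerase family, at -0.37. With the background model refitted, a change made after the counts were seen, 30 genes were called, 20 higher and 10 lower, 10 of them shared with the 11. DDB_G0278667 (2.32, adjusted p = 0.00646) then passed, as did DDB_G0272706 (1.14, at least 1.62-fold with the planned values), the ABC transporter gene abcA5 (0.78, adjusted p = 0.00646) and cnrG (-0.34, adjusted p = 0.0474), while metap1 and pks13 had adjusted p of 0.0112 and 0.0031. The share of higher genes among those called was 81.8% with the planned and 66.7% with the refitted values. With all 40 arrays and the plate as a random block most were lower, 36 higher and 53 lower, so an excess of higher genes did not hold throughout. Leaving out 1 plate gave 2 to 20 genes, and probes above background on all 40 arrays, which leave out genes dim in one mix, gave 0 with limma and 617 of 7296 genes at an unadjusted p under 0.05. Of the 11 genes, only DDB_G0288419 and DDB_G0288417 kept the call in every alternative that tested them and without each plate in turn. The other 9 lost it with the replicate number as a block (adjusted p = 0.102 for each), with the slide as a fixed block and with the sample in Cy3 alone, where metap1 and pks13 had adjusted p of 0.288 and 0.288, and of 0.0579 and 0.338. With median centring in place of loess 7 of the 11 lost it, metap1 and pks13 among them (adjusted p = 0.624 for both). pks13 also lost it with the plate as a random block (adjusted p = 0.0508). metap1 lost it without any 1 of 13 plates, namely either plate of self 4, 8, 12 or 20 h or of chimera 8 h, self 16 h replicate 1, chimera 12 h replicate 2 or chimera 20 h replicate 2, and pks13 without 11 of these, all but self 4 h replicate 1 and self 16 h replicate 1 (adjusted p from 0.0518 to 0.0858). DDB_G0283429 and DDB_G0281695 lost it without any 1 of 13 plates, and DDB_G0288951 of 15.

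At 4 h, 16 genes differed between the mixes, 7 higher and 9 lower in chimeras, and the largest differences with a symbol were in pks13, apeA, tmem33 and metap1. pks13 was at 2.02 ± 0.13 (SD, n = 2) in chimeras, above background on 4 of 4 arrays, and on 0 of 4 in self mixes, where it was at -0.07 ± 0.02. It was at least 3.26-fold higher (log2 difference 2.10 ± 0.12, SE, adjusted p = 2.37e-06). apeA (DDB_G0277701) was at -0.20 ± 0.02 in chimeras and 1.79 ± 0.04 in self mixes, a difference of -1.99 ± 0.31 (adjusted p = 0.0323), while at 8 h it was at 2.01 ± 0.33 and 1.32 ± 0.15. tmem33 (DDB_G0286009), for a predicted membrane protein, was lower by -1.21 ± 0.21 (adjusted p = 0.0441), and metap1 by -1.03 ± 0.13 (adjusted p = 0.00913). With the refitted model 47 genes were called, 15 of them shared with the 16, tmem33 no longer passed (adjusted p = 0.0978) and the other 3 did (adjusted p from 6.69e-07 to 0.0176). Leaving out 1 plate gave from 2 genes, without self 4 h replicate 2 or chimera 4 h replicate 1, to 146, without chimera 4 h replicate 2, and the slide as a fixed block left 1. All 4 lost their calls with median centring in place of loess (adjusted p = 0.136, 0.136, 0.154 and 0.258 for pks13, apeA, tmem33 and metap1) and in a fit of the 4 plates of 4 h alone (adjusted p from 0.26 to 0.434). apeA, tmem33 and metap1 lost them with the slide as a fixed block (adjusted p = 0.381 for each), and metap1 with the replicate number as a block (adjusted p = 0.053). tmem33 lost its call as well with the processed signals, the deposited table, the brightest probe per gene and the sample in Cy3 alone (adjusted p from 0.0506 to 0.34). pks13 kept its call without each plate in turn. metap1 lost it without self 4 h replicate 1 or chimera 4 h replicate 1 (adjusted p = 0.052 and 0.0925), apeA without chimera 4 h replicate 1 or either plate of self 4, 12, 16 or 20 h (adjusted p from 0.0527 to 0.177), and tmem33 without these 9 or either plate of self 8 h or chimera 12 h (adjusted p from 0.0516 to 0.224).

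At 8 h, 2 genes were called, both higher in chimeras, DDB_G0281695 at 1.97 ± 0.28 (SE, adjusted p = 0.0485, at least 3.09-fold) and DDB_G0283213 at 1.53 ± 0.21 (adjusted p = 0.0485). The second of these was at 0.48 with the refitted model and no longer passed, and 5 genes did then, among them DDB_G0288419, DDB_G0288417 and DDB_G0283429. Both self plates of 8 h held an array of distorted background, and neither chimera plate did. Genes at an unadjusted limma p under 0.05 at 8 h fell from 864 with the planned values to 142 with the refitted model. Neither of the 2 genes called as planned passed with no filter on dim probes, the brightest probe per gene or median centring in place of loess. The same held with the replicate number as a block, the slide as a fixed block, the sample in Cy5 alone or the 4 plates of 8 h alone. Their adjusted p over these alternatives went from 0.052 to 0.583. With the slide as a random block 2 genes were called at 8 h. Without any 1 of 15 plates, all but chimera 8 h replicate 2 and those of chimera 12 and 16 h, both planned genes missed the threshold. With the sample in Cy3 alone DDB_G0281695 missed it as well (adjusted p = 0.0501), and DDB_G0283213 did with the processed signals and with the deposited table (adjusted p = 1 for both). The refitted model with the replicate block ended both calls (adjusted p = 0.0695 and 1). At 12 and 16 h limma called 0 genes with the planned values. The unadjusted p was under 0.05 for 459 and 191 of 10022 genes, below the share of 0.05 that chance alone gives on average. The refitted model called 4 and 3 genes, where DDB_G0288419 (adjusted p = 7.21e-05 and 0.000104) and DDB_G0288417 (adjusted p = 0.00848 and 0.00729) were higher. DDB_G0288419 was not above background on any self array, and its planned values put it at least 33.8-fold and 35.4-fold higher at 12 and 16 h. Without chimera 16 h replicate 1, 164 genes were called at 16 h, and without chimera 8 h replicate 2, 117 at 8 h. At 20 h, 2 genes were called, both lower in chimeras. The chimera plate called replicate 1 was behind at this time on the first component. The balance of directions changed with the processing. There were 25 higher and 12 lower with the processed signals, and 16 higher and 11 lower with the deposited table. Lower genes were the majority with the refitted model (6 higher, 17 lower) and the plate as a random block (42 higher, 53 lower). They were so too without the 6 arrays of distorted background (2 higher, 9 lower) and in the refit with the replicate block (29 higher, 40 lower). The 2 planned calls were fscJ and tssc1. fscJ (DDB_G0292102), for a receptor of the frizzled and smoothened-like family, was at 0.54 ± 0.10 (SD, n = 2) against 1.66 ± 0.28 in self mixes, a difference of -1.12 ± 0.15 (SE, adjusted p = 0.0363). tssc1 (DDB_G0274279) was at -0.83 ± 0.07 against 0.03 ± 0.16, a difference of -0.87 ± 0.12 (adjusted p = 0.0363). Both still passed with the refitted model, in which 23 genes were called, and neither passed with several alternatives, for which adjusted p are given for fscJ and then tssc1. These were median centring in place of loess (0.69 and 0.25), the deposited table (0.07 and 0.0513), the replicate number as a block (0.0813 and 0.104), the slide as a fixed block (0.416 and 0.466), the sample in Cy3 alone (0.386 and 0.23) and the 4 plates of 20 h alone (0.659 for both). fscJ did not pass with the processed signals (adjusted p = 0.0788), nor tssc1 with the sample in Cy5 alone, with probes above background on all 40 arrays or without the 6 arrays of distorted background (adjusted p from 0.085 to 0.0942). Both missed the threshold without any 1 of 10 plates, namely self 20 h replicate 1 (adjusted p = 0.428 and 0.478), chimera 20 h replicate 1 or either plate of self 4, 8 or 12 h or chimera 4 h (adjusted p from 0.0562 to 0.0982), and tssc1 also without self 20 h replicate 2 or either plate of chimera 12 h. Without chimera 20 h replicate 2 the count at 20 h was 353.

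**Figure D4:**
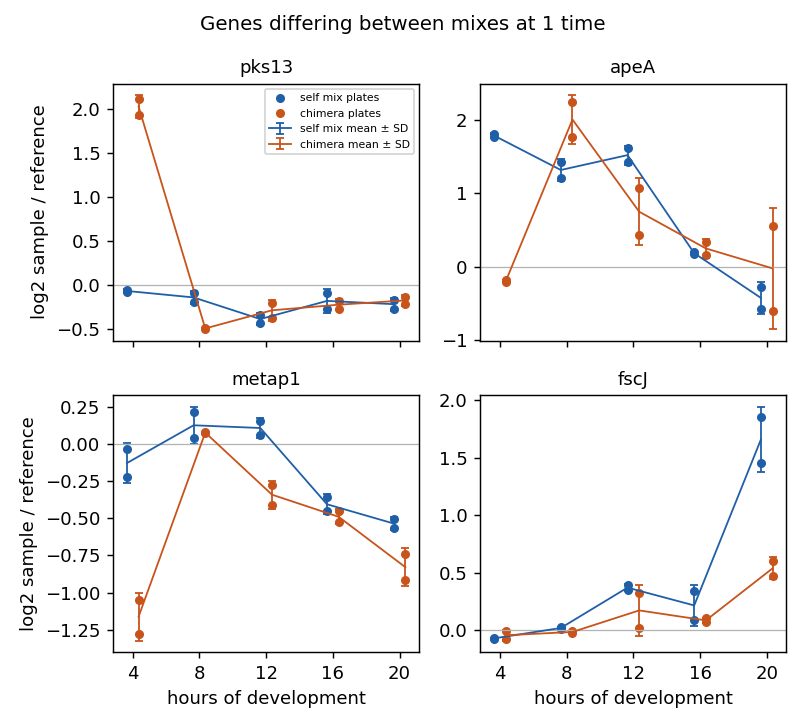
Log2 ratio of sample over reference (vertical axes) against hours of development (horizontal axes) for genes called between mixes at 4 h (pks13, apeA and metap1) or at 20 h (fscJ). Points are plates, lines join the means of 2 plates of the self mix (blue) and the chimera (orange), and bars are 1 SD. In chimeras pks13 was at 2.02 at 4 h, and at 20 h fscJ was at 0.54 against 1.66 in self mixes.

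Whether the difference between mixes itself differed between times was tested by the interaction, which passed for 1 gene, pks13 (adjusted p = 0.000167). With the refitted model it passed for 3, pks13, DDB_G0288419 (adjusted p = 0.0171) and DDB_G0272436 (adjusted p = 0.00257). For the other genes called at single times a difference between the times was not shown. The interaction of pks13 did not pass with median centring in place of loess (adjusted p = 0.909), with the slide as a fixed block (adjusted p = 0.332) or with the replicate number as a block (adjusted p = 0.0722).

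Averaged over the 5 times, the medians of the gene lists lay between -0.20 and 0.10, while differences at single times were larger for some lists. Only 1 member of any list, pks13, passed in the averaged comparison. With camera 7 of 19 lists differed from the other genes. None of the 7 did with an estimated correlation, a test that passed no list between 4 and 20 h either. Lysosomal and bacteria-digesting enzymes were below 0 in 14 of 15 cases, with a median of -0.17 (adjusted p = 0.000248, and adjusted p = 0.64 with an estimated correlation), and ctsB at -0.45, cprE at -0.41 and ctsZ at -0.39 were the lowest. The cytosolic ribosomal proteins were below 0 in 71 of 71 cases with a median of -0.20 (adjusted p = 2.37e-07), and the proteasome subunits in 33 of 38 with a median of -0.18 (adjusted p = 0.000202), each with an adjusted p = 0.896 with an estimated correlation. Mitochondrial ribosomal proteins (10 of 11 below 0, median -0.11, adjusted p = 0.00522), respiratory chain subunits (19 of 22, median -0.11, adjusted p = 0.0126), and heat-shock proteins and chaperonin (14 of 21, median -0.14, adjusted p = 0.0247) were below the other genes with camera as well. Polyketide synthases were above 0 in 11 of 17 cases (median 0.08, adjusted p = 0.0383). With an estimated correlation these 4 had an adjusted p from 0.69 to 0.896. None of the 7 passed with fry or in the exact permutation of mixes within times, where the lysosomal list had the smallest p at 0.0139, or 0.264 after adjustment over the lists. Adjusted over the list alone, 5 heat-shock and chaperonin genes, 2 lysosomal genes, 1 histone and 1 polyketide synthase gene passed. The 12 other lists had medians from -0.12 to 0.10 and camera adjusted p of 0.173 or more. The prestalk list had a median of 0.02 and a mean of -0.01, and the ABC transporters had a median of -0.00207 and a mean of 0.00816 with a downward test.

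With camera 6 lists went both ways between single times, and 2 of them, the cytosolic ribosomal proteins and the DNA replication genes, did so with the refitted model too. All 71 cytosolic ribosomal protein genes lay below 0 at 4, 12 and 16 h, with medians of -0.40, -0.76 and -0.83, and all 71 lay above 0 at 20 h, with a median of 0.90 (camera adjusted p from 5e-44 to 2.99e-05). With an estimated correlation none of these held (adjusted p = 0.997, 0.528, 0.286 and 0.953 at 4, 12, 16 and 20 h). At 8 h, 69 of 71 were above 0 with a median of 0.14 (camera adjusted p = 0.306, and 0.0296 with the refitted model). DNA replication genes were below 0 in 24 of 28 cases at 8 h (median -0.24) and above 0 in 26 of 28 at 12 h (median 0.50), with adjusted p = 0.866 and 0.528 with an estimated correlation. Polyketide synthases were below 0 in 15 of 17 cases at 8 h (median -0.29, camera adjusted p = 0.00707) and above 0 in 13 and 14 of 17 at 12 and 16 h (camera adjusted p = 0.018 and 0.00406), with adjusted p from 0.369 to 0.866 with an estimated correlation. With the refitted model their median at 8 h was -0.03 and the calls at 8 and 12 h were lost (camera adjusted p = 0.411 and 0.16), while that at 16 h held (adjusted p = 0.00194) and the list was up at 4 h (adjusted p = 0.0265). The actin cytoskeleton was up with camera at 12 h and down at 16 h, aggregation genes were up at 4 h and down at 16 h, and counting factor and cheater genes were down at 16 h and up at 20 h (adjusted p from 4.74e-06 to 0.0481), with adjusted p from 0.286 to 0.997 with an estimated correlation. With the refitted model actin at 12 h (median 0.01 in place of 0.06), aggregation at 16 h and counting factor genes at 16 h no longer passed (camera adjusted p = 0.191, 0.154 and 0.2). Calcium-binding cbp proteins were above 0 in 10 of 11 cases at 4 h (camera adjusted p = 0.0126, and adjusted p = 0.402 with an estimated correlation). In all, camera passed 6, 2, 10, 11 and 2 lists at 4, 8, 12, 16 and 20 h, and 7, 2, 8, 8 and 2 with the refitted model. With an estimated correlation none passed at any time (adjusted p of 0.13 or more among those lists). fry passed 1, the mitochondrial ribosomal proteins at 4 h, which were below 0 in 11 of 11 cases (median -0.42, adjusted p = 0.0164). At 16 and 20 h, where the ribosomal medians had opposite signs, the 2 chimera plates were 30.6 and 39.3 apart on the first component. At each of these times 1 of them scored near plates of the other time.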

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

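Of the tests below, those on slides, on background correction and loess, and on probes of genes that rise together were chosen after the result was seen, and the test on partner RNA was chosen before.

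The difference between chimeras and self mixes of the polyketide synthase gene pks13 was not the same at all times (interaction, adjusted p = 0.0001666). At 4 h it was at least 3.26-fold higher in chimeras, where 4 of 4 chimera arrays and 0 of 4 self arrays were above background, and at the other times its probes were not above background in either mix. The interaction passed with each plate left out in turn, and did not pass with median centring in place of loess (adjusted p = 0.909), with the slide as a fixed block (adjusted p = 0.332) or with the replicate number as a block (adjusted p = 0.0722).

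By the scanner's flags, 6 genes had a probe well above background on at least 15 of 20 chimera arrays and on at most 1 of 20 self arrays, led by DDB_G0288419 and DDB_G0288417, and 0 probes showed the reverse. Other probes of these genes can be above background in some self mixes, as 2 of DDB_G0288417 were on 5 of 20 self arrays, against 20 of 20 chimera arrays. Each slide held 2 chimera and 2 self arrays, so a shift of a whole slide has no part in the averaged differences, and that these were the same with the slide as a fixed block follows from the balance. With that block the calls of DDB_G0283429 (2.18, SE 0.33 before and 0.31 after) and DDB_G0281695 (0.84, SE 0.12 and 0.13) ended, with 6 in place of 10 residual degrees of freedom. Since the genes were picked for the pattern, they were picked again on the arrays of one dye orientation, at least 8 of 10 chimera and 0 of 10 self arrays, and measured on those of the other. The arrays with the sample in Cy5 gave the same 6 genes, and those with it in Cy3 gave 5 of them, without DDB_G0281695. On the other arrays and with the slide as a block the smallest averaged difference was 3.77 of its standard errors. That value is no further evidence on a shift of whole slides, which the balance had already removed. Background correction or loess is argued against, as in median-centred ratios of uncorrected signals on the other arrays the differences were 0.69 to 3.93 on the log2 scale, the smallest relative to its error at 4.05 standard errors. Both orientations hold RNA of the same plates, so this excludes nothing that acted before labelling. For RNA of the partner strain NC28.1 left in the sorted cells, the share of single probes that parted from their gene's other probes upward in chimeras was 1, but it rested on 1 probe, and for induction in the sorted strain by its partner 0 of 6 genes had 1 probe rising by over 1 log2 while another stayed within 0.5, which both explanations allow, so they cannot be told apart here, with neither the partner's sequence nor an unmixed NC28.1 sample at hand.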

How the results depend on the processing

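Alternatives named here as refitted, without 6 arrays, and refitted with the replicate block were chosen after seeing the data, and all others before. For the single genes named, 1938 comparisons of 54 test results with alternatives gave 1771 with the same direction and side of the threshold, 114 weaker, 16 stronger, 0 reversed and 37 with another sign where nothing was called. Most of the 54 were changes from 4 to 20 h or averaged differences not called, so these totals say little about calls between mixes. The totals for genes and lists also count Aquantile scaling, which moved no log ratio, and fits without 1 plate. Many of those plates lay outside the groups compared, so part of the agreement was given in advance. With left-out plates set aside, calls of genes with a symbol at single times were lost in 2 (pks13, 4 h) to 9 (tssc1, 20 h) of 18 alternatives. For lists, 1292 comparisons of 38 results gave 1180 the same, 41 weaker, 6 stronger, 1 reversed and 64 with another sign where nothing was called. The 15 genes named for the largest changes from 4 to 20 h kept direction and call in every alternative run. The counts between mixes depended on the processing, and except where said the cause was not tested.

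In the order averaged, 4, 8, 12, 16 and 20 h and interaction, the counts of genes were 42, 93, 9, 7, 4, 37 and 4 with the processed signals and 36, 69, 9, 7, 3, 27 and 3 with the deposited table, each sharing 9 of the 11 averaged genes. The median of 20 h minus 4 h over all genes was 0.03 with the planned values and -0.18 with the deposited table, which is not centred. They were 30, 47, 5, 4, 3, 23 and 3 with the refitted background model, 21, 66, 6, 3, 3, 11 and 3 without the 6 arrays of distorted background, and 89, 312, 45, 3, 2, 95 and 75 with all 40 arrays, a dye term and the plate as a random block. The refitted model with the replicate block gave 80, 330, 0, 1, 3 and 69 for the averaged comparison and the 5 times.

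Median centring in place of loess gave 0 genes at 4 h, 1 at 8 h, 0 at 20 h, 0 for the interaction and 3 lists. No filter on dim probes gave 27 at 4 h, 0 at 8 h and 2 at 12 h. Probes above background on all 40 arrays, which test fewer genes, gave 0 averaged, 0 at 8 h, 0 at 20 h and 0 for the interaction (limma). The brightest probe per gene gave 10 at 4 h, 0 at 8 h, 1 at 12 h and 1 at 16 h. The replicate number as a block, which treats plates of one number as paired, gave 3 averaged, 0 at 8 h, 0 at 20 h and 0 for the interaction, where pks13 had an adjusted p of 0.0722. The slide as a fixed block gave 2 averaged, 1 at 4 h, 0 at 8 h, 0 at 20 h and 0 for the interaction. Arrays with the sample in Cy5 alone gave 72 at 4 h, 0 at 8 h, 4 lists and a first component difference of -4.75, and those in Cy3 alone gave 2 averaged, 7 at 4 h, 1 at 8 h, 1 at 16 h, 0 at 20 h and 2 for the interaction. A trended and robust variance gave 85 at 4 h, and a fit of 2 groups alone gave 0 at 4 h and 0 at 20 h, with fewer samples. Where limma called 0 genes under these alternatives, 34 to 1340 genes had an unadjusted p under 0.05. Chance alone gives on average a share of 0.05 of the genes tested, and several of these counts lay below it. Whether plates of one number are pairs stays open. The correlation across genes of the replicate differences of the mixes was 0.274, 0.845, 0.229, 0.0537 and 0.625 at 4, 8, 12, 16 and 20 h with the planned values, and 0.570, 0.893, 0.198, 0.352 and 0.653, above 0.1 at each time, with the refitted model. Neither the planned fit nor the other splits of the plates took pairs into account.

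Leaving out 1 plate, with a lone plate assumed to vary like the other groups, gave 2 to 20 averaged, 2 to 146 at 4 h, 0 to 117 at 8 h, 0 to 1 at 12 h, 0 to 164 at 16 h, 0 to 353 at 20 h, 1 to 3 for the interaction, 4618 to 6218 for 20 h minus 4 h, 1 to 8 lists between mixes, 8 to 8 lists for development and a first component difference of -3.19 to 4.33. The averaged count was 2 without self 4 h replicate 2 or either plate of self 8, 12 or 20 h, 3 without self 16 h replicate 1, chimera 8 h replicate 2 or chimera 20 h replicate 2, 4 without chimera 8 h replicate 1, 5 without chimera 12 h replicate 2 or chimera 20 h replicate 1, 7 without self 4 h replicate 1 or chimera 12 h replicate 1, and 20 without chimera 16 h replicate 1. At 4 h it was 2 without self 4 h replicate 2 or chimera 4 h replicate 1, 4 without either plate of self 12 or 20 h, 5 without either of self 16 h, 9 without self 4 h replicate 1, 25 without either of chimera 16 h, 52 of chimera 20 h and 56 of chimera 8 h, and 146 without chimera 4 h replicate 2. At 8 h it was 117 without chimera 8 h replicate 2, 16 without either plate of chimera 12 h, 4 without either of chimera 16 h, 1 without chimera 8 h replicate 1 and 0 without any of the other 14 plates. At 12 h it was 1 without either plate of chimera 8 or 16 h. At 16 h it was 164 without chimera 16 h replicate 1, 3 without replicate 2 and 1 without either plate of chimera 8 h. At 20 h it was 353 without chimera 20 h replicate 2, 8 without either plate of self 16 h, 1 without self 20 h replicate 2, chimera 20 h replicate 1 or either of chimera 12 h, and 0 without self 20 h replicate 1 or either plate of self 4, 8 or 12 h or chimera 4 h. The interaction gave 3 without chimera 20 h replicate 2 and 2 without self 4 h replicate 1, chimera 8 h replicate 2, chimera 16 h replicate 1 or chimera 20 h replicate 1. Lists fell to 1 without chimera 20 h replicate 2 and to 4 without self 16 h replicate 1 or chimera 16 h replicate 2. The DNA replication list reversed to 0.073 without chimera 8 h replicate 1, with a range of -0.0812 to 0.073.

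Not run were the lists with a random block, which camera does not take, and 20 h minus 4 h with the replicate block, as no block holds both times. Aquantile scaling moved no log ratio. Signal limits what a bright reading can exclude, as 69.9% to 88.5% of probes were well above background on an array.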

Other observations

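The test of the bright background was chosen after the result was seen, and the tests of stages of development and of other splits of the samples were chosen before.

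Within self mixes the steps between times differed in size. Between 4 and 8 h 3166 genes changed, 1736 up and 1430 down, between 12 and 16 h 239, and between 16 and 20 h 48, of which 44 rose. Between 8 and 12 h limma called 0 genes with the planned values and 505 with the refitted background model, which called 4642, 1690 and 30 at the other steps. Fixed lists that were too small to test held hssA, which rose by 4.69 on the log2 scale between 4 and 20 h, and the discoidin gene dscE, at -3.24.

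Differences between the mixes at single times may come from plates at different stages of development. Across genes, the chimera minus self difference correlated with the self change from the time before to the time after with r of 0.690 at 16 h, 0.316 at 12 h and 0.126 at 8 h, and with 0.696, 0.346 and -0.065 with the refitted model. A shift in stage had been taken to need 0.5 or more at each of the 3 times, which did not hold. That rule cannot decide on 1 plate off stage at a single time, and 20 h, with no later time, was not tested. The 16 h value lay above 0.5. Cytosolic ribosomal proteins, which fell in self development (median -4.15), had -0.83 at 16 h and 0.90 at 20 h. These signs go with the chimera plate ahead at 16 h and that behind at 20 h. The proteasome, which also fell (-2.63), had -0.46 and 0.04. Neither list passed with an estimated correlation at these times. The question stays open at 8 and 12 h. A delay or an advance caused by the partner was not tested apart from a shift in stage.

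Compressed log ratios on 6 arrays are consistent with a few spots of very bright local background pulling the background model. After the refit without such spots the lowest correlation between dye orientations of a plate was 0.922, against 0.563 before.

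Splits of the plates within times into 2 groups, 100 with the real one, tested whether the averaged count can come from chance. With the planned values 4 splits, the real one included, gave as many genes as the real 11, just under the limit set before. The highest other count was 171 and the median 0. With the refitted model 14 splits gave as many as the real 30, which lay over that limit. The highest other count was then 278 and the median 1. The planned values hold the arrays of distorted background and the splits took no pairs into account, so chance was not excluded. Splits that call several times the real count point to some structure of the plates, and which one was not tested.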
